A study of Homo sapiens with 8 samples.

How the data were processed

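Gene expression was measured with Illumina bead arrays, 1 array for each of 8 lung tissue samples, 4 labelled as IPF and 4 as normal. Per the labels' protocols, total RNA was extracted with a column kit, copied into double-stranded cDNA and then into biotin-labelled cRNA. The labels give no pairing of samples, no slide and no scan batch, so none was modelled. Samples were named by group and a replicate number, assigned here within each group in deposited order. These replicate numbers are not those in the sample titles, which end in a number or letter of their own.

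A non-normalized and a normalized table were used. The deposited non-normalized table holds, per the file headers, an intensity and a detection p-value for each of 47223 probes on each array. Its deposited intensity values run from 70.4 to 34129 on a linear scale, are all above 0 and have medians that differ between arrays, so that they carry no background subtraction or normalization between arrays. The deposited detection p-value is a multiple of 1 over 770, as a rank among 770 background values would be. The second deposited table, with 47315 probes, holds linear intensity values with nearly equal medians on all arrays, from 143.9 to 144.0. Within each array its ranks equal those of the non-normalized intensities (Spearman correlation of 1, against at most 0.907 for another array), so it is a between-array normalization of the same signals. Its 92 additional probes have no gene name and values up to 155.4. Software versions for scanning and summarising are not given in the sources used here.

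Background was corrected by normexp with parameters taken from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale (limma 3.58.1 in R 4.3.3). A probe was kept when its detection p-value was under 0.05 on at least 4 of 8 arrays, whatever their group, which left 19994 probes. Gene symbols came from the platform annotation, which gives 1 symbol for 30110 probes, several for 8 and none for 17105. Symbols of 30071 probes were looked up again through their gene number in a RefSeq gene table, and 0 changed. Of the detected probes 15462 had 1 gene, and each gene was represented by its probe with the highest mean, giving 11889 genes, 2943 of them with more than 1 detected probe. Detected probes without a symbol, 4510 in number, were tested apart. No coordinates are given, since the files name no genome build. The number of probes detected per array ranged from 18386 to 21573.

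IPF lung was compared with normal lung by a linear model on the log2 values with empirical Bayes moderation (lmFit and eBayes, limma), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. SE is the moderated standard error. A gene not detected on any array of 1 group has only a bound there, given as "at least" a fold. Lists of genes, 41 in number, were fixed before the data were examined, as were the comparison, its test, 28 alternatives and the rule for naming genes. Of the lists 40 had at least 5 tested members, and the list of cartilage and bronchial wall genes did not. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, on ranks, and with fry. List scores were compared by an exact permutation test over all 70 assignments of 4 against 4, whose smallest two-sided p is 0.0286. Some genes stand in more than 1 list, such as 7 of the tested members of the matrix list.

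The genes named are the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, up to 4 members past the threshold of each list (or the 2 with the smallest p where none passed, given as values), and a fixed set of genes often studied in IPF. XIST, TSIX and Y-linked genes were left out before the test, so no count includes them. Left out of naming alone were classical HLA genes, antigen receptor segments and genes that follow a common deletion. No named gene had probes past the threshold in opposite directions. With each probe tested on its own, 1 of 2 detected probes passed for ECM2, SFRP4, MZB1, RRM2B, PMEPA1 and GPIHBP1. The same held for 1 of 3 for CXCL12 and PGM5, and 0 of 2 for MERTK. The probe with the smaller change gave 1.43 for ECM2, 1.10 for SFRP4, 0.52 for MZB1 and 1.29 for RRM2B. All detected probes passed for MMP7, POSTN, PRG4, AURKA, TP53INP1 and CD163, which had more than 1.

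The steps were tested on simulated data built from the 11889 genes of this comparison, with 200 genes changed in each of 5 runs. The fit recovered 29.9% of genes changed by 1 on the log2 scale, 83.9% of those changed by 2 and 98.2% of those changed by 3, and 3.82% of its calls were false. A matrix list moved by 1 was called in 5 of 5 runs with the preset correlation, the estimated correlation and fry alike. With the preset correlation 1 of 170 tests of other lists was called. The simulated genes varied independently of each other, whereas the estimated correlation in the real lists reached 0.75 for the motile cilium list. These runs therefore do not measure the error rate of the list tests in the real data.

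Alternatives covered the background correction and offset, normalization by median scaling or cyclic loess, the deposited normalized values, the detection filter, the summary of probes, array weights, the variance prior, the threshold, list scores as covariates, the list test and leaving out each array in turn. All 35 splits of the 8 arrays into 4 and 4 were fitted in the same way.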

Results

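The series profiled messenger RNA in whole human lung tissue. It set 4 samples from lungs with idiopathic pulmonary fibrosis (IPF), a chronic disease in which scar tissue replaces the walls of the air sacs, beside 4 samples of normal lung. Total RNA was copied into biotin-labelled RNA and hybridised to Illumina bead arrays, 1 array per sample. Between 20134 and 21573 probes were detected on the IPF lung arrays at a detection p-value under 0.05, and between 18386 and 20220 on the normal lung arrays. The median bead signal before normalization lay between 146 and 150 on the IPF lung arrays and between 122 and 158 on the normal lung arrays. The number of arrays limits the precision of every value given here. The labels do not state that the samples of a group came from separate donors, so the p-values measure only the spread between these samples, which may in part be technical.

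The only comparison the design holds is IPF lung against normal lung, and the series asks which genes are expressed differently in IPF. SFRP2, a secreted Wnt modulator made by fibroblasts, rose by 4.85 on the log2 scale (SE 0.40, 28.9-fold, adjusted p = 0.000643), from 6.44 ± 0.81 to 11.29 ± 0.50 (log2 signal, mean ± SD, n = 4 per group). MMP7, a matrix metalloproteinase made by epithelial cells, rose by 4.82 (SE 0.68, adjusted p = 0.00673). S100A12, a calcium-binding protein of neutrophils, fell by 5.01 (SE 0.64, adjusted p = 0.00462), from 10.01 ± 1.59 in normal lung to 5.0 ± 0.45 in IPF lung. SAA1, an acute phase protein, fell by 4.60 (SE 0.68, adjusted p = 0.00894). Each of these genes was not detected on every array of its lower group, and the size of its change depends on the background step. In the submitters' normalized values, which show no background subtraction, the log2 changes were 3.67 for SFRP2, 3.55 for MMP7, -3.19 for S100A12 and -2.90 for SAA1, all past the test.

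Of 11889 genes tested, 180 were higher and 133 lower in IPF lung at an adjusted p under 0.05 (limma), and 2374 had an unadjusted p under 0.05. In 307 of these 313 genes all 4 IPF lung samples lay on one side of all 4 normal samples. Such a separation was seen in 11.6% of all tested genes, and chance alone gives 2.86%. The change was at least 2-fold in 176 of the higher and 128 of the lower genes. All 313 genes had the same sign in each of the 8 fits that left out 1 array. A gene whose groups do not overlap can hardly change sign in this way, so for 307 of them this adds little. Of the 313 genes, 97 passed the test in all 8 fits. The counts were 94 higher and 58 lower without IPF lung replicate 1, 78 and 58 without IPF lung replicate 2, 117 and 75 without IPF lung replicate 4, and 68 and 55 without normal lung replicate 1. With medians equalised in place of quantile normalization 240 genes were higher and 93 lower, so that the share of higher genes went from 57.5% to 72.1%, and the median of all genes moved to 0.14 on the log2 scale.

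**Figure D1:**
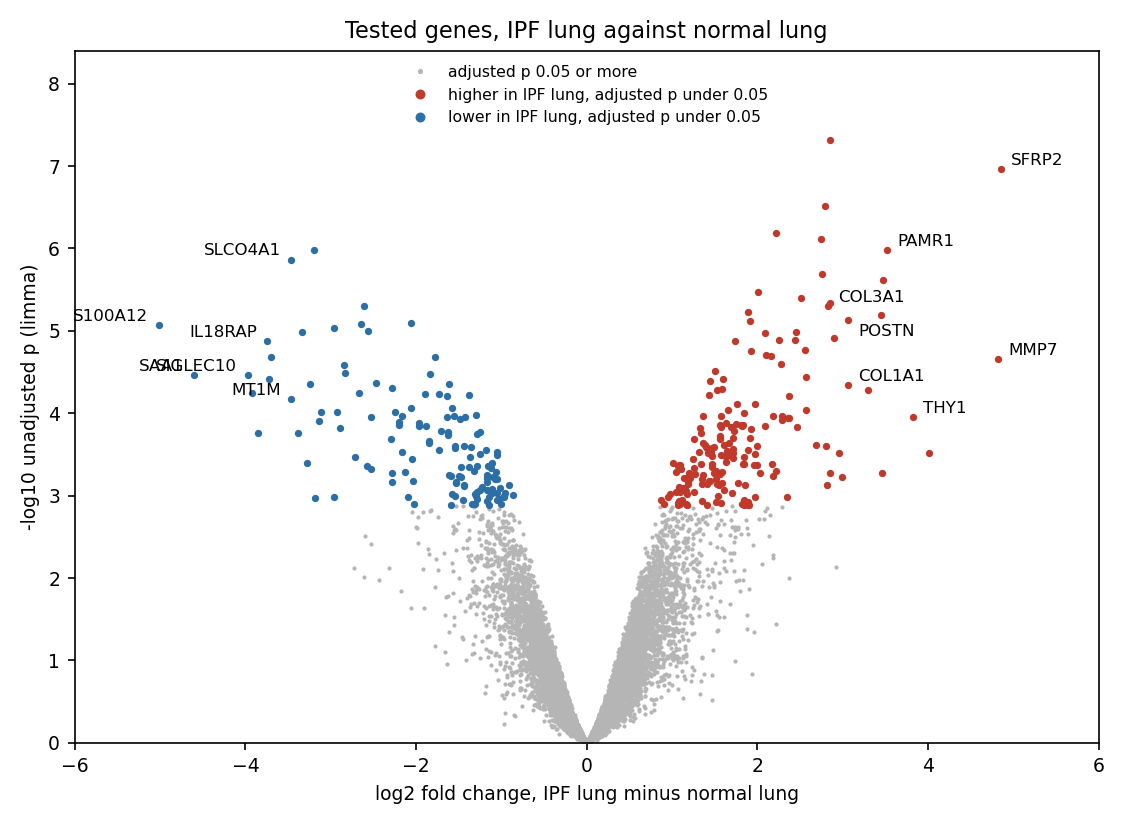
Each point is 1 of 11889 tested genes, with the log2 fold change of IPF lung over normal lung on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. Red points are the 180 genes higher and blue points the 133 genes lower in IPF lung at an adjusted p under 0.05, with SFRP2 at 4.85 and S100A12 at -5.01 farthest out on each side.

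The other genes with the largest rises were of several kinds. THY1, a surface protein of fibroblasts, rose by 3.82 (SE 0.65) and LINC02538, a long non-coding RNA, by 4.01 (SE 0.77). The matrix genes ECM2, COMP, POSTN and COL1A1 rose by 3.47 (SE 0.39), 3.30 (SE 0.51), 3.06 (SE 0.38) and 3.06 (SE 0.47). SFRP4, a further secreted Wnt modulator, rose by 2.95 (SE 0.57), APLNR, the receptor for apelin, by 3.45 (SE 0.43) and JSRP1, a sarcoplasmic reticulum protein, by 3.0 (SE 0.63). PAMR1 was detected on all 4 IPF lung arrays and on 0 of the normal ones, and was at least 8.41-fold higher in IPF lung (adjusted p = 0.00178). A bound of this kind sets the mean of the brighter group against the lowest signal detected on each array of the dimmer group, or the probe's own signal where that was higher. It depends on the background step, and for PAMR1 it was 3.27-fold with no background correction and 5.30-fold with an offset of 50. Several of these genes were near background in normal lung, where MMP7, ECM2 and COMP were detected on 2 of 4 arrays and JSRP1 on 1. LINC02538 (adjusted p = 0.0235), JSRP1 (adjusted p = 0.0325) and SFRP4 (adjusted p = 0.0232) did not pass with no background correction or when certain single arrays were left out. These arrays were IPF lung replicate 2 or 3 or normal lung replicate 1, 3 or 4 for LINC02538, IPF lung replicate 2 or normal lung replicate 1, 2 or 3 for JSRP1, and IPF lung replicate 1, 2 or 4 or normal lung replicate 1 or 4 for SFRP4.

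The 12 largest falls held further neutrophil genes. PROK2, a chemokine-like peptide of neutrophils, fell by 3.92 (SE 0.62), and MMP25, a metalloproteinase on the neutrophil surface, fell by 3.38 (SE 0.61). SIGLEC10, a sialic acid-binding receptor of immune cells, fell by 3.97 (SE 0.59), IL18RAP, a subunit of the interleukin 18 receptor, fell by 3.74 (SE 0.50), and PI3, the elastase inhibitor elafin, fell by 3.72 (SE 0.56). The organic anion transporter gene SLCO4A1 fell by 3.46 (SE 0.37), the metallothionein gene MT1M fell by 3.46 (SE 0.56), the sugar transporter gene SLC2A11 fell by 3.34 (SE 0.44) and haptoglobin, HP, fell by 3.28 (SE 0.65). The probe for DEFA1, a neutrophil defensin, was detected on 0 of the IPF lung arrays and was at least 7.93-fold lower there (adjusted p = 0.00657), or at least 3.15-fold with no background correction. DEFA1 and its near-identical copies cannot be told apart by such a probe, and the same uncertainty holds for SAA1, for MT1M and for the tryptase gene TPSB2. S100A12 and SAA1 were detected on 1 of 4 IPF lung arrays, PROK2 on 2, and PI3 and HP on 3. Over the alternatives the log2 changes went as small as -2.64 for SIGLEC10, -2.41 for PROK2, -2.62 for IL18RAP and -2.25 for PI3. The smallest were -2.40 for SLCO4A1, -3.00 for MT1M, -2.42 for MMP25, -2.13 for SLC2A11 and -2.35 for HP.

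**Figure D2:**
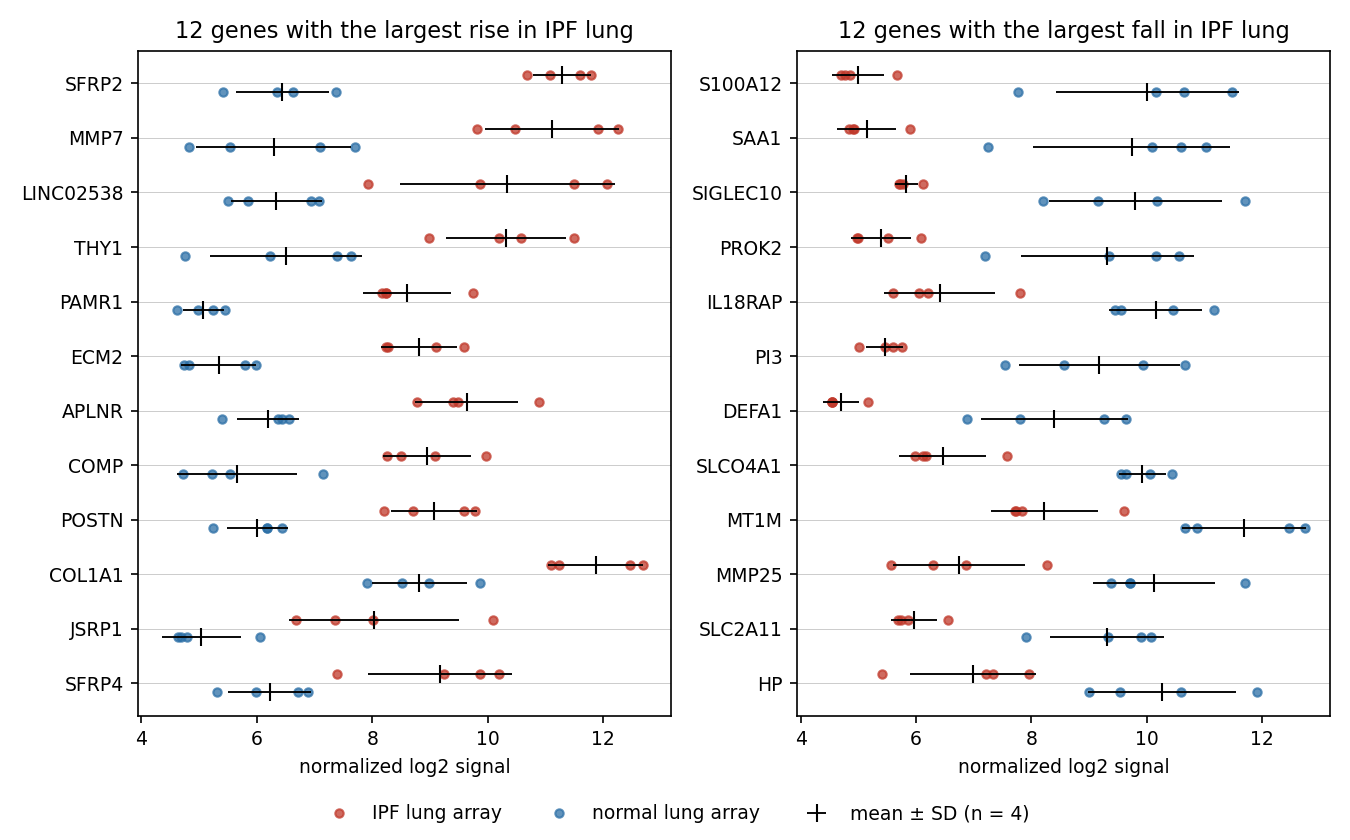
Normalized log2 signal (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall in IPF lung, among genes past the test whose groups do not overlap. Points are single arrays (red IPF lung, blue normal lung) and black marks show the mean with 1 SD over 4 arrays. SFRP2 averaged 11.29 in IPF lung and 6.44 in normal lung, and S100A12 averaged 5.0 and 10.01.

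Many interstitial matrix genes rose in IPF lung. Of 42 tested members of the list of fibrillar collagens and interstitial matrix, 14 rose and 0 fell, and 30 rose and 1 fell when adjusted over the list alone. The median member was 1.16 higher, 36 of 42 were positive, and the list passed the camera test, which asks whether a list's genes moved more than other genes (adjusted p = 3.99e-16, and adjusted p = 0.228 with an estimated correlation). COL3A1, a fibrillar collagen, rose by 2.83 (SE 0.34, adjusted p = 0.00399), and COL1A1 from 8.82 ± 0.83 to 11.88 ± 0.82. Fibronectin, FN1, differed by 0.59 (SE 0.27, adjusted p = 0.253). Its probe read near background, with median signals before normalization of 188 in IPF lung and 146 in normal lung, and a further probe gave 0.09. These values therefore do not show that FN1 was unchanged. With any 1 array left out the list held 11 to 16 rising members, 11 of them without normal lung replicate 1. It held 7 with no detection filter, 6 with a detection p-value under 0.01 on all 8 arrays and 9 with the contractile score as a covariate. The list score, the mean deviation of a list's genes on each array, was 0.68 ± 0.33 in IPF lung and -0.68 ± 0.23 in normal lung, a difference at the smallest p an exact permutation of 4 against 4 samples can give (two-sided p = 0.0286, 0.127 after adjustment over 40 lists).

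The list of smooth muscle and myofibroblast contractile genes had a median of 0.39 with 1 of 18 members risen, also when adjusted over the list alone (camera adjusted p = 0.0460, and adjusted p = 0.824 with an estimated correlation). That member was PGM5, a protein of muscle adhesion sites, at 1.17 (SE 0.26), while ACTA2, the smooth muscle actin of myofibroblasts, differed by 0.28 (SE 0.25, adjusted p = 0.575). In the basement membrane list 2 of 15 members rose, 4 adjusted over the list alone (camera adjusted p = 0.0460, and adjusted p = 0.736 with an estimated correlation). The contractile list passed camera under 12 of 25 alternatives and the basement membrane list under 8 of 26. Both calls were lost with median scaling, with cyclic loess and without IPF lung replicate 3 or 4 or normal lung replicate 1 or 3, the contractile call also without normal lung replicate 4 and the basement membrane call also with no background correction. The rising basement membrane genes were COL4A5 with 1.98 (SE 0.32) and AGRN, agrin, with 1.32 (SE 0.23). Of 12 matrix metalloproteinases 2 rose and 2 fell, 4 and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.394). MMP7 and MMP11 were higher, MMP11 by at least 2.37-fold since no normal array detected it (1.43-fold with no background correction), and MMP25 and MMP9 were lower, and MMP9 fell by 3.18 (SE 0.72). PGM5 did not pass without normal lung replicate 1, 3 or 4 or IPF lung replicate 1, 2 or 4, which left 0 contractile members, and AGRN did not pass without IPF lung replicate 1, which left 1 basement membrane member. The count of falling metalloproteinases was 0 without IPF lung replicate 2 and 1 without IPF lung replicate 1 or 3 or normal lung replicate 1, 2 or 3.

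Signalling lists linked to fibrosis each held members that rose. In the list of TGF-beta ligands, activators and targets 4 of 18 members rose, and 9 rose and 1 fell adjusted over the list alone (median 0.70, camera adjusted p = 0.000409, and adjusted p = 0.376 with an estimated correlation). LTBP2, a matrix protein related to the fibrillins, rose by 2.16 (SE 0.30), the ligand gene TGFB3 by 1.63 (SE 0.28), PMEPA1, a TGF-beta target, by 1.43 (SE 0.27) and ITGAV, an integrin chain, by 1.36 (SE 0.29). In the Wnt pathway list 3 of 28 members rose and 1 fell, 6 and 2 adjusted over the list alone (median 0.55, camera adjusted p = 0.0103, and adjusted p = 0.376 with an estimated correlation). The list mixes ligands, receptors and Wnt-binding proteins, so its shift does not measure Wnt signalling. Its rising members were SFRP2 and SFRP4, which bind Wnt proteins and also stand in the matrix list, and the ligand gene WNT10A. The last was at least 1.66-fold higher and not detected in normal lung. WNT10A did not pass with no background correction, an offset of 50, the submitters' normalized values or no detection filter. The Wnt list did not pass camera with a detection p-value under 0.01 on all 8 arrays (mean shift 0.02, adjusted p = 0.869) or with the contractile score as a covariate. The receptor gene FZD5 fell by 1.44 (SE 0.31). In the list of the insulin-like growth factor axis 2 of 10 members rose, 4 adjusted over the list alone (median 0.68, camera adjusted p = 0.00407, and adjusted p = 0.228 with an estimated correlation). IGF1, the growth factor itself, rose by 1.84 (SE 0.31), and IGFALS, a subunit of its serum carrier, by 0.91 (SE 0.21, adjusted p = 0.0494). Of 21 senescence and p53 targets 2 rose, 8 adjusted over the list alone (median 0.52, camera adjusted p = 0.000301, and adjusted p = 0.141 with an estimated correlation). These were RRM2B, a ribonucleotide reductase subunit, with 2.10 (SE 0.29) and TP53INP1, a p53-induced nuclear protein, with 1.39 (SE 0.26). Scores of this list were 0.32 ± 0.07 in IPF lung and -0.32 ± 0.05 in normal lung. Their difference had an exact permutation p of 0.0286 (two-sided) and did not pass when adjusted (adjusted p = 0.127). Without normal lung replicate 1, and likewise without IPF lung replicate 2, these lists held 2 rising TGF-beta, 1 rising and 0 falling Wnt, 1 rising growth factor and 1 rising senescence member. The TGF-beta count was also 2 without IPF lung replicate 1 or 4 or normal lung replicate 4, IGFALS did not pass without any 1 of the 8 arrays, and FZD5 did not pass without IPF lung replicate 1 or 4 or normal lung replicate 2 or 4.

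Several neutrophil and monocyte genes fell in IPF lung. Of 22 tested members of the list of neutrophils and classical monocytes 8 fell and 0 rose, 14 fell adjusted over the list alone, and all 22 were negative, with a median of -1.69 (camera adjusted p = 7.81e-16, and adjusted p = 0.244 with an estimated correlation). S100A8, a subunit of calprotectin, fell by 3.20 (SE 0.33, adjusted p = 0.00178), from 13.94 ± 0.51 to 10.74 ± 0.53. The list score was -0.94 ± 0.21 in IPF lung and 0.94 ± 0.73 in normal lung. This difference had an exact permutation p of 0.0286 (two-sided) and did not pass when adjusted (adjusted p = 0.127). Normal lung replicate 1 had the highest score of the normal arrays, and without it 7 members fell, within a range of 6 to 11 over all arrays left out in turn. With no detection filter 4 members fell and with a detection p-value under 0.01 on all 8 arrays 5 did. Erythroid genes, which mark blood, had mean scores of -0.04 ± 0.39 in IPF lung and 0.04 ± 0.90 in normal lung. Single normal lung arrays ran from -1.14 to 1.05, so these means do not fix the blood content of either group.

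Macrophage lists were mixed. In the list of macrophage genes reported in fibrotic lung 4 of 16 members fell, and 1 rose and 4 fell adjusted over the list alone. CHI3L2, a chitinase-like protein, fell by 3.24 (SE 0.50), CD163, the haptoglobin-haemoglobin scavenger receptor, fell by 1.61 (SE 0.34) and MERTK, a receptor for dying cells, fell by 1.16 (SE 0.27), beside MMP9. Of these 4, CHI3L2 passed with any 1 array left out, and the list held 1 falling member without IPF lung replicate 1 or normal lung replicate 1, 3 without IPF lung replicate 3 and 2 without each of the other arrays. The list's median was 0.41 while its mean was -0.18, and it did not pass (camera adjusted p = 0.908). SPP1, osteopontin, differed by -0.10 (SE 0.71, adjusted p = 0.957) and CHI3L1 by -0.18 (SE 0.35, adjusted p = 0.824). In the alveolar macrophage list 1 of 21 members rose, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.740). It was OLR1, a receptor for oxidised lipoprotein, with 2.37 (SE 0.41), and the chemokine gene CCL18 differed by 1.96 (SE 0.86, adjusted p = 0.237).

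A few genes of B cells, T cells, antigen presentation and mast cells rose in IPF lung. Of 13 tested B cell and plasma cell genes all were positive and 2 rose, 4 adjusted over the list alone (median 0.72, camera adjusted p = 0.000413, and adjusted p = 0.376 with an estimated correlation). JCHAIN, the joining chain of secreted antibodies, rose by 3.46 (SE 0.71) with overlapping groups, and MZB1, a plasma cell chaperone, by 2.29 (SE 0.39). In the T cell list CD27, a costimulatory receptor, was the single member of 16 to rise, by 2.22 (SE 0.45), and 2 rose adjusted over the list alone (median 0.72, camera adjusted p = 0.00315, and adjusted p = 0.736 with an estimated correlation). In the list of dendritic cells and class II genes 2 of 17 rose, and 6 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00553, and adjusted p = 0.627 with an estimated correlation). HLA-DOA rose by 1.99 (SE 0.40) and HLA-DOB by 1.82 (SE 0.32), and the pair encodes a modulator of peptide loading in B cells. CD27 and HLA-DOB were each detected on 1 normal lung array, and over the alternatives their changes went as low as 1.06 and 0.82. In the list of mast cells, basophils and eosinophils 1 of 11 rose, and 7 rose and 2 fell adjusted over the list alone (median 1.56, camera adjusted p = 0.0378, and adjusted p = 0.627 with an estimated correlation). It was the tryptase gene TPSB2 with 1.85 (SE 0.42), whose groups overlapped. JCHAIN, CD27 and TPSB2 did not pass with no background correction, the submitters' normalized values, no detection filter or the contractile score as a covariate. Without normal lung replicate 1 the T cell, class II and mast cell lists held 0 members past the test and the B cell list held 1. The B cell count was 1 without every other array but IPF lung replicate 3 and normal lung replicate 3, which gave 3 and 2. The T cell count was 2 without either of these 2 arrays and 0 without any other, and the class II count was 5 without IPF lung replicate 3, 0 without IPF lung replicate 2 and 1 without IPF lung replicate 1 or normal lung replicate 2 or 4. TPSB2 passed without normal lung replicate 2 and did not pass without any of the other arrays. The mast cell list did not pass camera without IPF lung replicate 4 or normal lung replicate 1 or 4. With a detection p-value under 0.01 on all 8 arrays the T cell, class II and mast cell lists did not pass camera.

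Of the other immune lists none passed the camera test. CXCL12, a stromal chemokine, was the 1 of 11 lymphoid chemokine genes to rise, by 2.09 (SE 0.37), with 2 adjusted over the list alone (camera adjusted p = 0.467), while CXCL13 differed by 0.06 (SE 0.24, adjusted p = 0.918). The CXCL13 probe was detected on 3 IPF lung arrays and 1 normal lung array, so its value was read near background. Of 22 acute phase and inflammatory cytokine genes SAA1 fell and ICAM1, an adhesion molecule, rose by 1.72 (SE 0.31), with 2 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.161). Of 26 complement genes C4BPA rose by 2.0 (SE 0.38), and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.740). CXCL12 did not pass without normal lung replicate 1, nor ICAM1 without IPF lung replicate 2, nor C4BPA without IPF lung replicate 2 or 4 or normal lung replicate 1. No member passed, also when adjusted over the list alone, among 16 natural killer and cytotoxic genes (camera adjusted p = 0.968) or 29 interferon response genes (camera adjusted p = 0.394). CST7 and CTSW differed by -1.32 (SE 0.40) and 0.76 (SE 0.34), and IFITM3 and IFITM1 by -0.74 (SE 0.24) and -0.97 (SE 0.36). The interferon list passed camera under 2 of 26 alternatives, 1 of them without IPF lung replicate 3 (lowest adjusted p = 0.000884, mean shift 0.16 to 0.80 over all). The acute phase list passed downward under 3 of 26, without IPF lung replicate 4 or normal lung replicate 2 or 4.

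Alveolar epithelial genes did not pass the test in either direction. Of 19 type 2 cell genes 0 passed over all genes, and 3 rose and 1 fell adjusted over the list alone (median 0.46, camera adjusted p = 0.161). Of 16 type 1 cell genes 0 passed over all genes and 1 rose adjusted over the list alone (median 0.47, camera adjusted p = 0.0830). The type 1 list passed camera upward under 5 of 26 alternatives, among them without IPF lung replicate 4 or normal lung replicate 2 or 4 (lowest adjusted p = 0.00791). The type 2 list did so under 2 of 26, without IPF lung replicate 4 or normal lung replicate 2 (lowest adjusted p = 0.00579). The surfactant gene SFTPC differed by 1.15 (SE 0.31, adjusted p = 0.0846), with all 4 IPF lung samples above all 4 normal ones. PLA2G1B and SFTA3 of the type 2 list differed by 2.09 (SE 0.50, adjusted p = 0.0547) and 1.07 (SE 0.27, adjusted p = 0.0621). Of the type 2 genes 6 were negative, among them HHIP at -1.63 (SE 0.57), SDR16C5 at -1.58 (SE 0.47, adjusted p = 0.0309 over the list alone) and ABCA3 at -1.27 (SE 0.47), and these 3 were chosen after their values were seen. Among type 1 genes AGER, the receptor for advanced glycation products, differed by 0.48 (SE 0.50, adjusted p = 0.635), CAV1, caveolin, by 1.02 (SE 0.34, adjusted p = 0.139), AQP5 by 1.32 (SE 0.34, adjusted p = 0.0689) and PDPN by -0.95 (SE 0.30, adjusted p = 0.128). In the list of basal and basaloid epithelial cells 1 of 8 members rose, 2 adjusted over the list alone (camera adjusted p = 0.0627). It was the transcription factor gene SOX4 with 1.36 (SE 0.23, adjusted p = 0.0151). KRT5, a basal cell keratin, was detected on 1 array and the mucin gene MUC5B on 0, so neither was tested.

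Airway lists varied more between samples than between groups. Motile cilium scores were 0.04 ± 1.23 in IPF lung and -0.04 ± 0.30 in normal lung, and 0 of 23 members passed, also when adjusted over the list alone (camera adjusted p = 0.886). FOXJ1, the master regulator of ciliated cells, differed by -0.13 (SE 0.59, adjusted p = 0.932), TPPP3 by 1.28 (SE 0.37, adjusted p = 0.103) and DNAAF11 by 0.72 (SE 0.40). The mean shift of the cilium list was -0.44 without IPF lung replicate 1 (adjusted p = 0.00880) and 0.55 without IPF lung replicate 4 (adjusted p = 0.0114), and 0.86 with the contractile score as a covariate (adjusted p = 1.14e-06), over a range of adjusted p from 1.14e-06 to 0.999 for all its alternatives. Of 16 secretory and mucous airway genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.576), with BPIFA1 at -2.61 (SE 0.83, adjusted p = 0.129) and LTF at -0.89 (SE 0.65). The same held for 22 genes of epithelial adhesion and polarity (camera adjusted p = 0.884), with CLDN4 at -1.01 (SE 0.31) and PKP3 at -0.84 (SE 0.28), the latter positive with medians equalised, with cyclic loess, with no background correction and with the submitters' normalized values.

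Endothelial genes went different ways. Of 19 general endothelial genes 0 passed over all genes and 1 fell adjusted over the list alone, with 13 of 19 negative and a median of -0.66 (camera adjusted p = 0.00407, and adjusted p = 0.736 with an estimated correlation). The list also did not pass camera without IPF lung replicate 3 or normal lung replicate 2, and did not pass fry. CLDN5, a tight junction protein, differed by -1.29 (SE 0.31, adjusted p = 0.0554) and SOX17 by -1.29 (SE 0.37, adjusted p = 0.0999). Of 22 alveolar capillary genes APLNR rose and GPIHBP1, which anchors lipoprotein lipase to capillaries, fell by 2.53 (SE 0.51, adjusted p = 0.0291), with 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.487). GPIHBP1 passed when normal lung replicate 2 was left out and did not pass when any other array was, or with no background correction or with the submitters' normalized values. FCN3, a ficolin abundant in lung, differed by -0.79 (SE 0.32, adjusted p = 0.199). Of 14 systemic venous, arterial and lymphatic genes POSTN alone rose, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.999). Of 8 mesothelium and pleura genes PRG4, lubricin, rose by 1.56 (SE 0.27) and HP fell, with 1 rising and 2 falling adjusted over the list alone (camera adjusted p = 0.886). HP did not pass without IPF lung replicate 1, 2 or 4 or normal lung replicate 1 or 4, which left 0 falling members.

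Of 23 tested hypoxia and glycolysis genes 2 fell and 0 rose, 4 fell adjusted over the list alone, and 18 were negative (median -0.39, camera adjusted p = 0.000337, and adjusted p = 0.248 with an estimated correlation). ADM, the vasodilator adrenomedullin, fell by 2.20 (SE 0.38, adjusted p = 0.0162) and PFKFB4, a regulator of glycolysis, fell by 1.59 (SE 0.33, adjusted p = 0.0323), while GAPDH differed by -0.89 (SE 0.32, adjusted p = 0.169). In the unfolded protein response list 0 of 22 members passed over all genes and 2 fell adjusted over the list alone (median -0.40, camera adjusted p = 0.00793, and adjusted p = 0.627 with an estimated correlation), with TRIB3 at -1.53 (SE 0.39) and ASNS at -1.05 (SE 0.28). In the cell cycle list AURKA, a mitotic kinase, was the 1 of 19 members to rise, by 1.52 (SE 0.33), and 4 rose adjusted over the list alone (median 0.35, camera adjusted p = 0.00793, and adjusted p = 0.736 with an estimated correlation). ADM did not pass without IPF lung replicate 2, and PFKFB4 passed without normal lung replicate 2 and did not pass without any of the other arrays. AURKA did not pass without IPF lung replicate 1 or 2 or normal lung replicate 1, 2 or 3. The cell cycle list did not pass camera without IPF lung replicate 3 or normal lung replicate 2, nor the unfolded protein response list without IPF lung replicate 4.

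The remaining lists did not pass. Of 18 heat shock genes CRYAB, a small heat shock protein, fell by 1.10 (SE 0.23), and 2 fell adjusted over the list alone (camera adjusted p = 0.555). CRYAB passed when normal lung replicate 1 was left out and did not pass when any other array was, or with medians equalised. Of 25 lipid synthesis and handling genes 0 passed over all genes and 2 fell adjusted over the list alone (camera adjusted p = 0.161), with ACSL1 at -1.10 (SE 0.26, adjusted p = 0.0550) and FADS1 at -1.38 (SE 0.37). No member passed, also when adjusted over the list alone, among 23 immediate early and stress response genes (camera adjusted p = 0.268), 8 erythroid genes (0.740), 30 oxidative phosphorylation genes (0.968), 33 cytosolic ribosomal protein genes (0.886) or 12 DNA methylation enzymes and readers (0.406). Their members with the smallest p were SOCS3 at -1.12 and KLF2 at -0.95, SELENBP1 at 0.80 and ALAS2 at -0.73, NDUFS7 at -0.76 and NDUFS1 at 0.53, RPS2 at -0.77 and RPL14 at -0.60, and GADD45A at 0.97 and ZBTB4 at 0.65. ACTB, the cytoskeletal actin, differed by 0.01 (SE 0.19, adjusted p = 0.983).

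Over the 40 lists tested, 12 passed camera upward and 4 downward with a preset correlation between genes of 0.01. With a correlation estimated for each list 0 passed in either direction, 5 had an unadjusted p under 0.05 and the smallest adjusted p was 0.141. The fry test, which asks whether a list's genes moved one way on balance without setting them against other genes, passed 5 lists upward and 2 downward, all 7 among the 16. These were the matrix, TGF-beta, Wnt, insulin-like growth factor and senescence lists upward, and the neutrophil and hypoxia lists downward. Median, mean and camera direction differed in sign for the lists of alveolar capillary, systemic endothelial, fibrotic macrophage, erythroid, mesothelial, oxidative phosphorylation, ribosomal and epithelial adhesion genes.

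**Figure D3:**
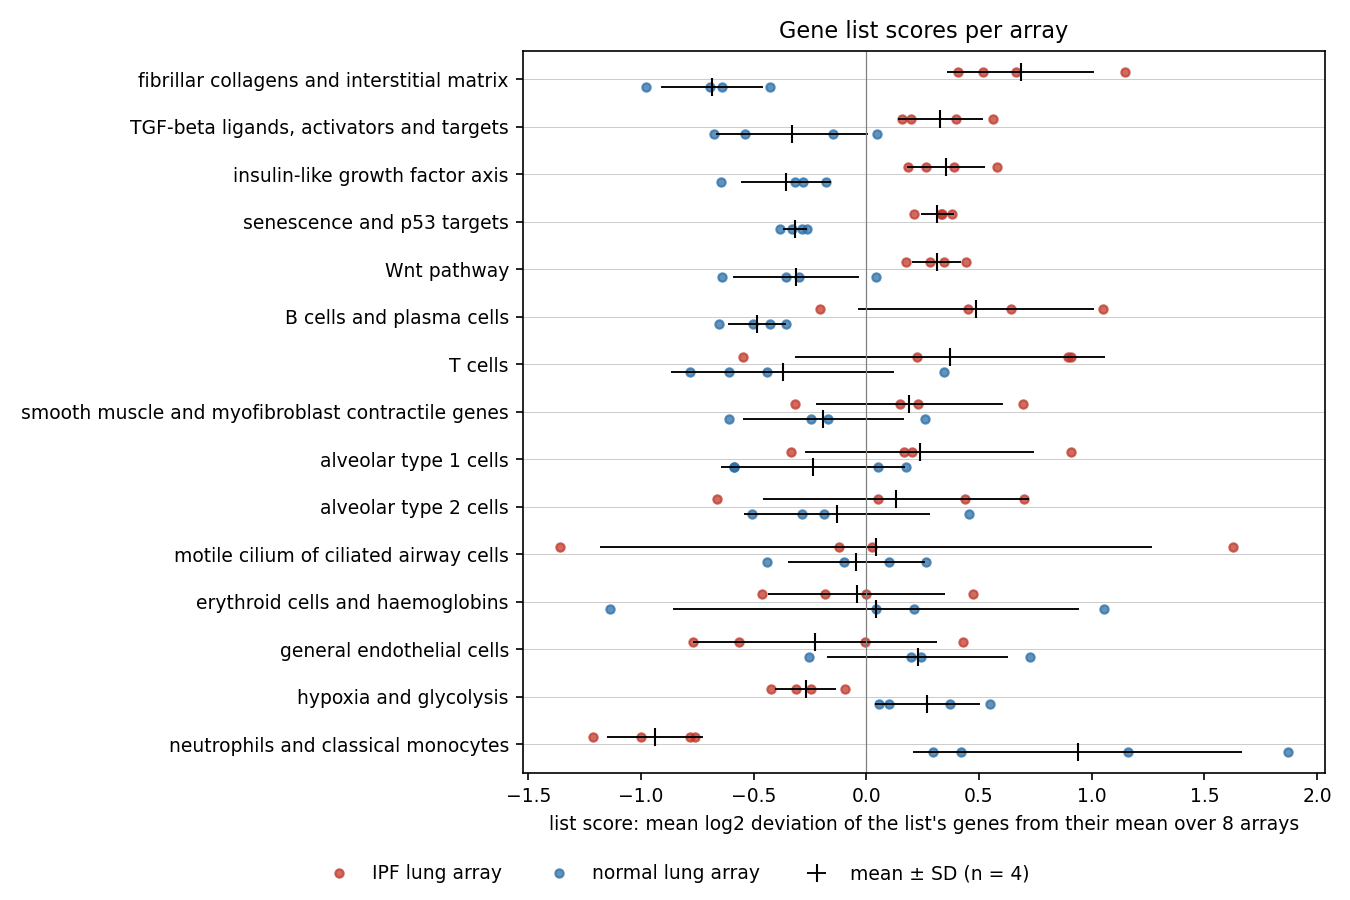
Score of 15 gene lists on each array (horizontal axis, mean log2 deviation of the list's tested genes from their mean over 8 arrays). Red points are IPF lung and blue points normal lung arrays, and black marks show the mean with 1 SD over 4 arrays. Matrix scores averaged 0.68 in IPF lung and -0.68 in normal lung, neutrophil scores -0.94 and 0.94, and motile cilium scores spread from 1 IPF lung array to the next with an SD of 1.23.

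Arrays resembled their own group more than the other. Pearson correlations over the tested genes lay between 0.931 and 0.963 within IPF lung, between 0.918 and 0.947 within normal lung and between 0.854 and 0.934 across groups. The first principal component held 37.6% of the variance and had all 4 IPF lung arrays on one side, from -39.6 to -22.1, and all 4 normal arrays on the other, from 12.1 to 65.3, with normal lung replicate 1 the farthest out.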

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

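The tests of blood by erythroid genes, of airway by motile cilium genes, of an acute inflammatory response and of 1 IPF lung sample rich in alveolar tissue, and the use of contractile scores as a covariate, were chosen after the data were seen.

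Single arrays stood far from the other 3 of their group in 23 of 288 groups of values checked, where chance marks about 1 in 20. On IPF lung replicate 4 the log2 signals of PAMR1 (9.74, next 8.24), S100A12 (5.67, next 4.85), DEFA1 (5.16, next 4.55), PRG4 (8.24, next 7.41) and SOCS3 (8.85, next 7.68) were the highest of the IPF lung arrays. On IPF lung replicate 3 SAA1 (5.90, next 4.92), SLCO4A1 (7.59, next 6.17) and MT1M (9.61, next 7.84) were the highest. The same array had the lowest score among IPF lung arrays for systemic endothelial genes (-0.49, next 0.21) and for interferon response genes (-0.77, next 0.49). PDPN was highest on IPF lung replicate 2 (9.56, next 8.80), and LTF (7.15, next 6.05) and NDUFS7 (10.35, next 10.01) on IPF lung replicate 1. On normal lung replicate 1 MMP25 was the highest (11.70, next 9.72) and RRM2B the lowest (5.33, next 6.21) of the normal arrays. On normal lung replicate 2 ACTA2 (13.28, next 12.84) and AGER (11.92, next 10.22) were the highest and APLNR was the lowest (5.39, next 6.37). On normal lung replicate 3 CD27 (5.94, next 5.05) and CXCL13 (5.94, next 5.32) were the highest and IGFALS (5.29, next 5.56) and KLF2 (12.48, next 13.30) the lowest. JSRP1 was highest on normal lung replicate 4 (6.05, next 4.78).

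Among 4510 detected probes with no gene name, which no comparison of genes used, 5 were higher and 4 lower in IPF lung by limma at an adjusted p under 0.05, and 588 had an unadjusted p under 0.05.

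Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as its 313 genes, and the highest count of any other split was 14. A first rank among 35 is the strongest result this test can give, which argues against a chance split but does not exclude it. The test cannot tell disease from any other difference between the groups. For gene lists 12 of the 35 splits gave as many as the real 16, with up to 21 in another split, so chance cannot be excluded for the number of lists.

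The 22 neutrophil and monocyte genes were all negative, 8 past the test, with a median of -1.69. If both sets of genes shifted alike, more blood in the normal samples would lower erythroid genes in IPF lung by about as much. That they shift alike was not tested. The erythroid median was 0.00983 (-0.45 to 0.37 with 1 array left out, SD 0.56 over 8 members, score difference -0.09, SE 0.49), which argues against blood as the whole cause only under that assumption. Of these members 4 were positive and 4 negative. Normal lung replicate 1 had the highest erythroid score (1.05) and the highest neutrophil score (1.87) of all arrays. Without normal lung replicate 1 the neutrophil and monocyte median was -1.33 (-1.47 to -1.03 with a further array left out), and every remaining normal array scored above every IPF lung array, which argues against 1 normal sample rich in neutrophils. An acute inflammatory response in the normal samples cannot be told apart from a lower neutrophil content of IPF lung, because acute phase and cytokine genes had a mean of -0.39 (-0.59 to -0.17 with 1 array left out, exact permutation p = 0.371, two-sided) that lay below 0 without separating the groups. The disease itself may also lower these genes, and that was not tested.

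Of 42 matrix genes 36 were positive, 14 past the test, with a median of 1.16. With the contractile score as a covariate the median was 0.88 (0.84 to 1.06 with 1 array left out). This argues against smooth muscle content as the whole cause only if the score tracks smooth muscle alone, which was not tested. The contractile list also holds myofibroblast genes, and the same covariate moved the mean shift of the motile cilium list from 0.09 to 0.86. The matrix list still passed camera with this covariate (adjusted p = 1.53e-12, between 6.76e-19 and 0.228 over its alternatives). That pass does not bear on the cause, since 12 of 35 splits of the arrays gave as many camera calls of lists as the real one. More airway in the IPF lung samples cannot be told apart from other causes, because motile cilium genes had a median of 0.0171 (-0.51 to 0.43 with 1 array left out) but scores that varied between arrays too widely to decide (score difference 0.09, SE 0.63). Fibrosis may raise these genes through more matrix-producing cells or through more expression per cell, a hypothesis that whole tissue cannot resolve and that was not tested.

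Alveolar epithelial genes were mixed and not lower on balance in IPF lung, with 6 of 19 type 2 and 4 of 16 type 1 members negative and a median of 0.47 over both. Saturation of bright probes could hide a loss. The dimmer part of these genes had a median of 0.66 (0.42 to 0.97 with 1 array left out), which argues against it for those genes. Some of them read near background, such as AQP5, detected on 1 normal lung array. The brightest probes were not tested for saturation, and SFTPC spanned only 14.31 to 14.41 on the IPF lung arrays. Without IPF lung replicate 2, the IPF lung array with the highest alveolar scores, the median of all members was 0.15 (0.10 to 0.39 with a further array left out). This lies too close to 0 for its spread to exclude that 1 sample rich in alveolar tissue carried the pattern. The site in the lung from which each sample was taken is not given in the sources used here, and no biological explanation was tested.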

How the results depend on the processing

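The motile cilium and contractile scores as covariates, and the counts of list members without normal lung replicate 1, were added after the data were seen. Genes higher and lower numbered 60 and 46 with no detection filter, where 19941 genes were tested and 100 of the 313 genes passed again. They numbered 90 and 81 with a detection p-value under 0.01 on all 8 arrays, where 8380 genes were tested, and 4 lists passed upward. At an adjusted p under 0.1 they numbered 365 and 284. With the contractile score as a covariate they numbered 82 and 60, and 118 of the 313 passed again; the cause was not tested. With an estimated correlation 0 lists passed upward and 0 downward, and with fry 5 and 2. Leaving out 1 array gave 68 to 152 genes higher and 55 to 127 lower, from fewer samples. The fewest came without normal lung replicate 1 (68 and 55), and IPF lung replicates 1 (94 and 58), 2 (78 and 58) and 4 (117 and 75) also moved the counts by more than 1.5 times. The shift of the motile cilium list ran from -0.44 without IPF lung replicate 1 to 0.55 without IPF lung replicate 4, and was -0.05 without normal lung replicate 2, 0.86 with the contractile score as a covariate and 0.45 with array quality weights; the cause was not tested. Median scaling gave 240 genes higher and 93 lower.

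SFRP2, MMP7, PAMR1, ECM2, APLNR, POSTN, COL3A1, LTBP2, RRM2B, COL4A5, MMP11, S100A12, S100A8, IL18RAP, DEFA1, SLC2A11 and SLCO4A1 passed the test under every alternative run for them. IGFALS passed under 4 of 22, MMP9 under 10 of 22, and MERTK and FZD5 under 10 of 23. Over the named genes and the alternatives that kept all arrays, 1366 values kept direction and side of the threshold, 113 lost the test, 19 gained it and 14 below it changed sign. With 1 array left out these were 672, 133, 14 and 13. For list shifts 630 kept both, 54 lost the test, 9 gained it and 19 changed sign below it. With 1 array left out these were 260, 17, 16 and 26, and the cilium list turned. The slide as a block was not run, since the files name no slides. No paired analysis was possible because the labels share no replicate numbers between groups. Genes near background, such as MMP7 in normal lung, have folds limited by the background of the array.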

Other observations

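Metallothionein genes were examined after the results were seen, and their test was chosen then. These genes encode small proteins that bind zinc and copper. Of 7 tested, 4 fell in IPF lung (limma). MT1M fell by 3.46 (SE 0.56, adjusted p = 0.0121), MT1X fell by 2.57 (SE 0.52, adjusted p = 0.0278), MT1G fell by 2.28 (SE 0.47, adjusted p = 0.0306) and MT2A fell by 1.31 (SE 0.30, adjusted p = 0.0494). MT1E differed by -1.33 (SE 0.32, adjusted p = 0.0590), MT1H by -1.17 (SE 0.53, adjusted p = 0.254) and MT1F by -0.46 (SE 0.35, adjusted p = 0.490). Groups did not overlap for MT1M, MT1G, MT2A and MT1E. All 7 were negative with quantile normalization, median scaling (5 past the test) and cyclic loess (5 past the test), and also with no background correction (2 past the test), the submitters' normalized values (2 past the test) and the contractile score as a covariate (1 past the test). With no detection filter 0 passed, and 1 passed when IPF lung replicate 1, IPF lung replicate 2, IPF lung replicate 4, normal lung replicate 1, normal lung replicate 3 or normal lung replicate 4 was left out. Metallothionein probes can bind transcripts of close relatives, so the 7 values are not independent.

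A hypothesis is that the metallothionein family as a whole may be lower in IPF lung. Among 403 families of genes that share a symbol stem, camera with the preset correlation passed 2, the collagens upward (28 tested, 5 past the test, median 0.98, adjusted p = 4.12e-07) and the metallothioneins downward (7 tested, median -1.33, adjusted p = 4.16e-05). With an estimated correlation the adjusted p was 0.991 for the collagens and 0.991 for the metallothioneins, so that chance among the many families cannot be excluded.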
